A study of Mus musculus with 2 samples.

How the data were processed

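Kidney tissue of adult C57BL/6J mice was measured by RNA sequencing in 2 libraries, replicate 1 and replicate 2 of 1 group named adult kidney. Per the labels, polyadenylated RNA depleted of ribosomal RNA and longer than 200 nt was sequenced as stranded paired-end reads of 76 nt on an Illumina GAIIx, with spike-in RNA added. The labels number the libraries as biological replicates, give 1 donor label for both, and give the health state as unknown. The same labels describe each sample as pooled from male and female littermates.

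The deposited gene and transcript tables are on the mouse build mm10 with annotation M4, per the text records deposited beside them. The aligner and the quantification program are not given in the sources used here. The authors deposited an expected count per gene and per transcript, which is an estimate of fragments and need not be whole. Per the file headers, the same tables give TPM (transcripts scaled to a common sum over genes and spike-ins) and FPKM (fragments scaled to transcript length and depth). The gene tables also hold deposited posterior mean values, the SD of each estimated count, and the bounds of a TPM interval, which are signal values of the quantification. Per the file headers, the transcript tables give the share of each isoform in its gene in percent. The junction and contig tables are on the older build mm9. Per the file headers and the values, a deposited count per splice junction is the sum of a pair of counts named R1 and R2, and no source used here assigns R1 or R2 to a replicate. The deposited contig table gives a signal level per contig and a whole-number score summed over the contig. That deposited score divided by length and level lay between 26.3 and 27.1 for all contigs. Both tables also carry a deposited score limited to 1000 and a measure between 0 and 1 of unstated meaning. Nothing on mm9 was joined by coordinate to anything on mm10, and no annotation of mm9 was used here.

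Gene names, types, positions and GC content came from GENCODE M21 on GRCm38, and gene lengths from the deposited tables. A symbol was found for 42462 of the 43346 gene identifiers (98.0%), and 884 had none. Rows with numeric identifiers (26248, all at 0) and 97 spike-in rows were left out of library sizes and gene tests. Spike-ins held 1.59% and 2.29% of the expected counts of replicates 1 and 2. Library totals over genes were 67252609 expected counts for replicate 1 and 87330097 for replicate 2. A count of 0 was read as an upper limit of 3 counts per library, which is 0.0446 and 0.0344 CPM in replicates 1 and 2. These limits and all ratio intervals (95%, exact binomial) cover counting error only, since the labels name no molecular identifiers.

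A gene was called detected at a TPM of 1 or more in both libraries. Ratios of TPM used a pseudocount of 1. Libraries were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 1.03 and 0.974. DESeq2 1.42.0 size factors served as an alternative. The biological coefficient of variation is the square root of the common dispersion from edgeR with an intercept only, after its default filter on expression. A difference between libraries was called for a gene with 10 or more counts in sum when a two-sided exact binomial test on rounded expected counts gave a Benjamini-Hochberg adjusted p below 0.05 and the absolute log2 ratio was 1 or more. A prior count of 0.5 was used for genes with a 0. This test compares the reads of a pair of libraries, not conditions. Gene counts with a deposited SD above 10% of the estimate in a library were called uncertain. Nuclear copies of mitochondrial genes were the nuclear genes for which at least 50% of the 31-base words of the longest transcript occur in mitochondrial transcripts.

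Before the data were examined, 44 gene lists, the tests, the alternatives and the choice of genes to name were fixed. The lists cover 23 nephron segments, cell types and neighbouring tissues, together with metabolism, hormones, injury, early response, heat shock, circadian time, proliferation, transcription factors, sex, RNA class and isoforms. The named genes were the 20 nuclear genes with the highest mean TPM, and the 4 highest members of each list. Members below 0.1 TPM in both libraries were named where a list had 3 or fewer of them. Of the genes that differed between libraries with a mean TPM of 5 or more, the 10 with the largest ratio in each direction were named. All members of the Y-linked, Xist, red blood cell and isoform lists were named, as were the highest and lowest detected spike-ins. Genes with no symbol were counted and not named. Genes named outside this rule are marked as such. Some genes that the rule would name are not reported here.

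The median log2(TPM + 1) of 22 segment, cell type and tissue lists was compared with that of the general proximal tubule list by a two-sided exact permutation of list membership over genes, adjusted by Benjamini-Hochberg over the 22 lists. The smallest p such a test allows depends on the list sizes. The shift of a list between libraries is its median log2 ratio of TPM minus the median of 10000 random lists of the same size, matched on mean expression in 20 bins. It was called outside when its percentile among the random lists lay below 2.5 or above 97.5, and it carries no p. For mitochondrial genes, random lists were also drawn from the 50 nuclear genes nearest in length and GC content. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps, and matplotlib 3.10.9 for plots.

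Each procedure was tested on simulated data first. For the genes that differ between libraries, the binomial test called 92 of 100 genes changed 3-fold, 100 of 100 changed 8-fold and 0 of 18480 unchanged genes. These counts were drawn with counting error alone, so the result does not cover calls that arise from a wider spread between libraries. For list shifts, 3 of 100 unmoved lists and 100 of 100 lists moved by 1 on the log2 scale fell outside. For the comparison with the proximal tubule, equal lists were called in 6% of runs and lists 3 SD apart in 98.5%. A simulated coefficient of variation of 0.1 was recovered as 0.0993, and one of 0.3 as 0.295.

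Alternatives covered the detection threshold and unit, the pseudocount, filters on low values, the scaling, the ratio limit, an edgeR exact test with an assumed coefficient of variation of 0.1, each library alone, the matching of random lists, the isoform share, and limits on junctions and contigs. Genes were treated as items and not as independent replicates. No test between groups was possible with 1 group, and the flags named A and C in the junction table were used only as names because their meaning is not given in the sources used here.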

Results

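The kidney of adult C57BL/6J mice, an inbred laboratory strain, was profiled at 8 weeks of age by sequencing of RNA labelled as polyadenylated. The labels give 1 group, adult kidney, with 2 biological replicates, each described as tissue pooled from male and female littermates. Both carry 1 donor label, so SDs and p-values measure only the spread between these libraries or between genes. The gene tables hold 67252609 expected counts for replicate 1 and 87330097 for replicate 2. With no second group, the data allow a description of the tissue and a comparison of the replicates. Values are given as mean TPM ± SD over both libraries (SD, n = 2) unless a library is named.

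The highest levels were those of genes of the mitochondrial genome, of its nuclear copies and of a few noncoding, proximal tubule and housekeeping genes. Among nuclear genes without mitochondrial sequence, Gpx3, which encodes a secreted glutathione peroxidase, was the highest, at 21584 ± 915 TPM (GRCm38 chromosome 11, 54902453 to 54910377). Kap, which encodes an androgen-regulated protein of the proximal tubule, followed among protein-coding genes at 6215 ± 90.5 TPM (chromosome 6, 133849851 to 133853762). Fxyd2 (5781 ± 328), a subunit of the sodium pump, and Miox (5774 ± 848), an inositol oxygenase of the proximal tubule, came next. Slc34a1 (5069 ± 1063), the main phosphate transporter of the apical membrane, and Klk1 (4398 ± 1509.6), a kallikrein of the connecting tubule, also ranked among the 20 highest nuclear genes.

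Of 43346 genes, 13108 reached 1 TPM in both libraries, and 12273 of these (93.6%) were protein-coding. Replicate 1 alone gave 13581 genes and replicate 2 alone 13521, and 886 genes passed in 1 library only. In both libraries, 1109 genes reached 100 TPM and 90 reached 1000 TPM. The housekeeping genes Gapdh (5651 ± 1002), Ftl1 (5373 ± 44.7), Rplp1 (5162 ± 347), Fth1 (4760.1 ± 139.5) and Atp5b (4442 ± 2001) completed the protein-coding members of the 20 highest. For Atp5b, TPM was 5857 in replicate 1 and 3027 in replicate 2, yet its TMM-scaled counts differed by a ratio of 0.886. The other members of the 20 highest were noncoding or pseudogenes. Among these, Gm29216 (36807 ± 3853), Gm10222 (15345 ± 6176), Gm28437 (11469 ± 194), Gm28661 (5440.3 ± 4499) and Gm10925 (4360 ± 2022) are nuclear copies of mitochondrial genes, and the last 3 have uncertain counts. Whether reads assigned to these copies arose from them or from the mitochondrial genome was not tested. Gm42418 (10879 ± 7855) and Rn7sk (9624 ± 5248) are noncoding, as are Rn7s2 (6401 ± 1153) and Rn7s1 (4961 ± 884), whose counts were uncertain. Of the 13108 detected genes, 138 (1.05%) had uncertain counts in a library.

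The 10 highest genes held 21.1% ± 5.50 of TPM (SD, n = 2), with 17.3% in replicate 1 and 25.0% in replicate 2, and the same genes held 12.4% of expected counts. They were mt-Co1, Gm29216, mt-Atp8, mt-Co3, Gpx3, Gm10222, mt-Cytb, Gm28437, Gm42418 and mt-Atp6. TPM divides counts by length, and mt-Atp8, a short gene, ranked there on 7185 expected counts in replicate 1 and 31437 in replicate 2. Gm42418 was 3.49-fold higher in replicate 2 (95% interval 3.48 to 3.5), at 5325 TPM in replicate 1 and 16434 in replicate 2, and differed by the test between libraries. The 13 mitochondrial protein genes together held 14.4% ± 4.68 of TPM (SD, n = 2), 11.1% in replicate 1 and 17.7% in replicate 2, but 8.87% ± 3.31 of expected counts (6.53% and 11.2%). The 7 nuclear copies held a further 7.59% ± 1.72. Without the mitochondrial genes and their copies, the 10 highest genes held 8.24% ± 0.134 of all TPM. The small spread of this sum hides opposite moves of its members. Gm42418 held 0.532% in replicate 1 and 1.64% in replicate 2, and Rn7sk 1.33% and 0.591%. Protein-coding genes held 83.8% ± 2.39 of TPM and spike-ins 2.73% ± 0.588.

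Genes of the proximal tubule, the segment that takes back most filtered solutes, were expressed at high levels in both libraries. In the general proximal tubule list, Slc34a1 was followed by the water channel Aqp1 (945 ± 262), by Ggt1 (679.7 ± 137) and by the endocytic receptor Lrp2 (244 ± 79.4). The early part of the segment was represented by Gatm (816 ± 97.1), the glucose transporter Slc5a2 (737 ± 108), the amino acid transporter Slc6a19 (680.5 ± 139) and the anion transporter Slc22a8 (391 ± 14.1). The late part was represented by Slc6a18 (245 ± 98.4), Atp11a (163 ± 65.4), Slc1a1 (65.98 ± 12.6) and Slc5a1 (25.7 ± 7.21). List medians were 162 ± 26.02 TPM for the general list, 268 ± 31.4 for the early list and 45.9 ± 9.93 for the late list. The late list also holds Slc7a13 (0.445 ± 0.177) and Cyp7b1 (1.385 ± 0.361), named outside the rule, which belong to the male-biased list too. Both lay far below the late median and lowered it.

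Genes of the loop of Henle and the distal nephron were also detected, led by Umod of the thick ascending limb, which encodes uromodulin, at 2556 ± 917 TPM. That list further held Egf (360.2 ± 92.6), Cldn10 (165 ± 16.9) and the sodium transporter Slc12a1 (144 ± 33.1), with a list median of 64.2 ± 12.6. In the thin limb list, with a median of 113 ± 21.1, Cryab (259 ± 1.73), Akr1b3 (178 ± 55.7) and Slc14a2 (113 ± 21.1) were highest. The distal convoluted tubule list had a median of 24.2 ± 15.7 and was led by the thiazide-sensitive transporter Slc12a3 (379 ± 187), then Wnk4 (105 ± 1.77), Pvalb (24.1 ± 15.8) and Klhl3 (11.5 ± 2.33). Pvalb, which is also a gene of fast skeletal muscle, was at 12.9 TPM in replicate 1 and 35.3 in replicate 2, where it set the list median, while Slc12a3 was 1.84-fold lower in replicate 2. In the connecting tubule list (median 113 ± 80.2), Klk1 was followed by S100g (334 ± 37.3), Calb1 (113 ± 80.2) and Slc8a1 (13.3 ± 2.81). Calb1 had 170.0 TPM in replicate 1 and 56.5 in replicate 2, yet its TMM-scaled counts differed by a ratio of 0.894. The principal cell genes Aqp2 (561 ± 99.6), Aqp3 (240.1 ± 46.3), Hsd11b2 (231 ± 37.5) and Scnn1b (58.6 ± 14.5) stood in a list with a median of 27.5 ± 5.81. The intercalated cell list (median 26.8 ± 3.35) was led by Atp6v1b1 (97.2 ± 18.1), Slc4a9 (74.7 ± 24.2), Slc4a1 (60.6 ± 0.905) and Aqp6 (40.5 ± 2.82).

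Cells outside the tubule had list medians below that of the proximal tubule, except for red blood cells. The podocyte genes Podxl (102 ± 4.96), Synpo (44.8 ± 7.42) and Nphs1 (24.7 ± 3.22) belonged to a list with a median of 15.96 ± 2.34 TPM. Ren1, which encodes renin, stood at 163 ± 55.1 TPM, while Nos1 (0.45 ± 0) and Ptgs2 (0.22 ± 0) of the macula densa stayed under 1 TPM and set that list's median at 0.45 in both libraries. Endothelium (median 35.6 ± 6.05) was led by Plvap (424 ± 69.97), Egfl7 (216 ± 26.1), Emcn (72.9 ± 0.5303) and Pecam1 (41.9 ± 2.69). Stroma (median 21.9 ± 2.48) was led by Dcn (71.3 ± 10.6), Col1a2 (48.3 ± 4.48), Pdgfrb (37.9 ± 6.13) and Col3a1 (21.9 ± 2.48), and smooth muscle (median 28.9 ± 15) by Acta2 (107 ± 64.8), Tagln (52.3 ± 27.4), Myh11 (5.45 ± 2.64) and Cnn1 (3.595 ± 3.56). The macrophage genes Lyz2 (52.1 ± 25.4), C1qb (39.5 ± 1.05), C1qc (33.6 ± 1.03) and C1qa (28.4 ± 0.799) had a list median of 28.4 ± 0.799. Red blood cell genes were high, with Hba-a2 (3270.4 ± 174), Hbb-bs (2493 ± 102), Hba-a1 (1367 ± 42.9), Hbb-bt (302 ± 29.8) and Alas2 (15.96 ± 0.587), and a list median of 1367 ± 42.9.

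Genes of tissues next to the kidney or brought by blood were low in most lists. The urothelium list (median 6.99 ± 2.05 TPM) was led by Upk1a (23.2 ± 8.58), Upk3a (15.9 ± 4.33), Upk2 (9.73 ± 2.73) and Upk1b (4.25 ± 1.38). The fat list (median 58.8 ± 11.5) held Cfd (1044 ± 474), Fabp4 (205 ± 1.37), Cidec (86.7 ± 26.6) and Ucp1 (221 ± 36.01), the uncoupling protein of brown fat. Liver genes had a median of 2.53 ± 0.127, with Apoa2 (14.5 ± 1.04), Alb (7.64 ± 0.771), Fga (3.75 ± 0.156), Serpina1c (2.53 ± 0.127) and Apoh (0.060 ± 0.0424). Apoh rested on 5 counts in replicate 1 and 2 in replicate 2. Exocrine pancreas genes had a median of 0.060 ± 0.0283, with Cela2a (0.245 ± 0.148), Ctrb1 (0.17 ± 0.0707) and Cpa1 (0.060 ± 0.0283), while Pnlip and Prss2 had 0 TPM in both libraries, which allows up to 3 counts in each. The lymphocyte (median 1.502 ± 1.58), adrenal gland (2.17 ± 2.89) and skeletal muscle (22.9 ± 32.2) lists had an SD above their mean, and their genes are given with the differences between libraries.

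Of the 22 segment, cell type and tissue lists compared with the general proximal tubule list, 20 had a lower median, and 10 of these differed from it by a two-sided exact permutation test. The median of the podocyte list was 9.39-fold lower (exact adjusted p = 0.00754) and that of the intercalated cell list 5.91-fold lower (exact adjusted p = 0.0107), on the TPM + 1 scale. The stroma median was 6.94-fold lower (exact adjusted p = 0.0215). That of the 3 juxtaglomerular and macula densa genes, set by Nos1 and Ptgs2 and not by Ren1, was 109-fold lower (exact adjusted p = 0.0462). The medians of the urothelium (21.5-fold), liver (44.9-fold), adrenal gland (61.7-fold), lymphocyte (65.9-fold) and skeletal muscle (22.2-fold) lists were lower at an exact adjusted p of 0.00754 each. The exocrine pancreas list was 149-fold lower (exact adjusted p = 0.0137). Each of these 10 lists was lower in both libraries. For the adrenal gland list the log2 difference was -5.07 in replicate 1 and -7.00 in replicate 2, and for the lymphocyte list -6.98 and -5.31. In replicate 2 alone, skeletal muscle no longer differed (difference -1.69 on the log2 scale, exact adjusted p = 0.382, the highest of its alternatives, against a lowest of 0.00366). With members at 1 TPM or more in both libraries, only the podocyte and intercalated cell lists differed. The stroma (-2.80), urothelium (-3.91), liver (-4.63), lymphocyte (-4.73) and adrenal gland (-5.48) lists then stayed lower on the log2 scale without passing, the juxtaglomerular list turned to 0.00751, and no skeletal muscle or pancreas gene was left.

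For the other 12 lists no difference from the proximal tubule was shown. The early proximal tubule list had a higher median by 0.76 on the log2 scale (exact adjusted p = 0.274), and the red blood cell list a higher one by 3.11 (exact adjusted p = 0.190). The log2 difference was -1.92 for the late proximal tubule (exact adjusted p = 0.226), -0.49 for the thin limb (exact adjusted p = 0.815), -1.29 for the thick ascending limb (exact adjusted p = 0.437) and -0.68 for the connecting tubule (exact adjusted p = 0.853). It was -2.49 for principal cells (exact adjusted p = 0.132), -2.17 for endothelium (exact adjusted p = 0.172), -1.49 for fat (exact adjusted p = 0.437) and -2.43 for macrophages (exact adjusted p = 0.0536). The macrophage list passed under 4 of 7 alternatives, among them replicate 2 alone (-2.27, exact adjusted p = 0.0474), with adjusted p between 0.0137 and 0.0981 over exact tests, so that its result depends on the processing. The distal convoluted tubule list (-2.82, exact adjusted p = 0.132) passed in replicate 1 alone (-3.62, exact adjusted p = 0.0420), within a range of 0.0420 to 0.232, and its median in replicate 2 was that of Pvalb, which rose together with skeletal muscle genes. The smooth muscle list (-3.18, exact adjusted p = 0.0641) passed in replicate 2 alone (-3.53, exact adjusted p = 0.0462), within a range of 0.0462 to 0.0999. The permutations exchange genes between lists, and genes are not independent replicates.

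**Figure D1:**
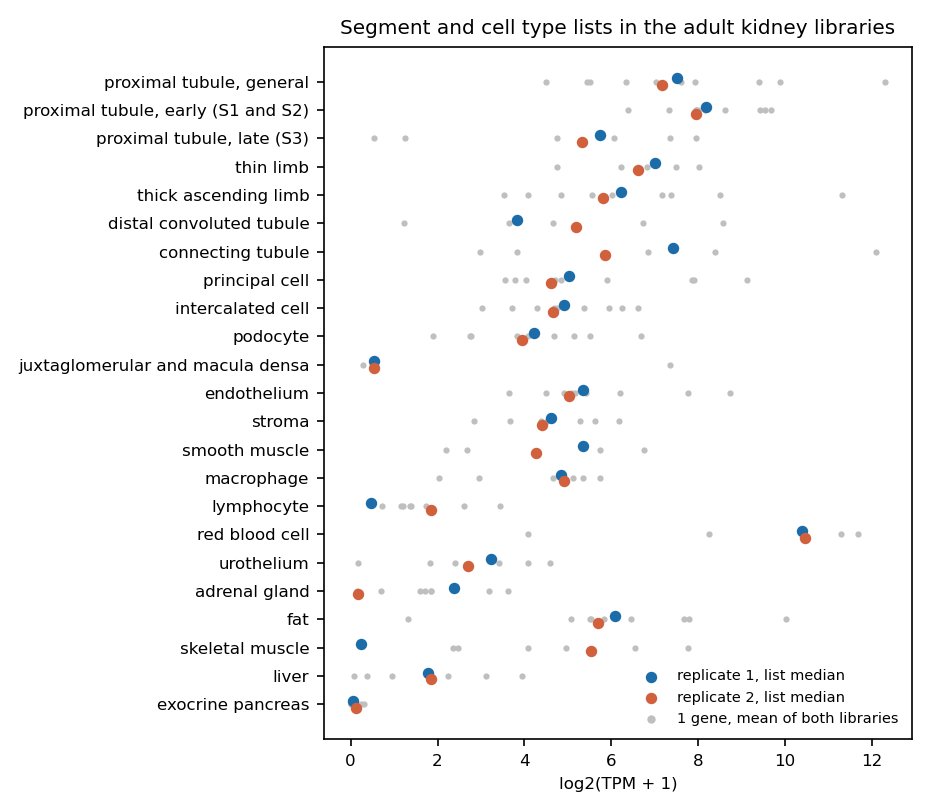
Level of the gene lists for nephron segments, cell types and neighbouring tissues as log2(TPM + 1), with coloured points for the list median in each library and grey points for single genes (mean of both libraries). Over both libraries the median was highest for red blood cells (1367 TPM) and lowest for exocrine pancreas (0.060 TPM).

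Metabolic genes were abundant. Gluconeogenesis, a function of the proximal tubule, was represented by Fbp1 (1154 ± 204), Pck1 (538 ± 54.8), G6pc (239.9 ± 12.1) and Pcx (202 ± 24.7), with a list median of 239.9 ± 12.1 TPM. Fatty acid oxidation genes (median 186 ± 8.499) were led by Hadh (352 ± 15.5), Acadm (273 ± 15.5), Acaa2 (269 ± 1.01) and Etfdh (223 ± 14.9). Glycolysis genes (median 288 ± 16.8) were led by Gapdh, Aldoa (1205 ± 157), Eno1 (570.0 ± 119) and Ldha (477 ± 51.97). Nuclear genes of oxidative phosphorylation had a median of 1009 ± 25.7, led by Atp5b, Atp5a1 (2473 ± 299.6), Cox4i1 (2323 ± 209) and Ndufa4 (1376 ± 18.7). The mitochondrial genes of the same pathway had a median of 5928 ± 2114, led by mt-Co1 (40089 ± 12789.5), mt-Atp8 (27090.3 ± 9449), mt-Co3 (25393 ± 6881), whose counts were uncertain, and mt-Cytb (13096 ± 4867).

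Hormone pathways and kidney transcription factors were represented in both libraries. In the renin-angiotensin-aldosterone list (median 64.7 ± 25.3 TPM), Ren1 was followed by Agt (82.7 ± 31.3), Ace (73.3 ± 39.99) and Agtr1a (56.05 ± 10.6). The endocrine list (median 28.9 ± 1.103) was led by the parathyroid hormone receptor Pth1r (519 ± 99.8), then Kl (112 ± 11.1), Vdr (75.8 ± 16.6) and Fgfr1 (28.9 ± 1.103). Among transcription factors (median 24.8 ± 0.615), Hnf4a (262 ± 39) was highest, and Pax8 (54.3 ± 4.23) and Tfcp2l1 (52.8 ± 2.33) were also expressed. All 11 transcription factors of the list reached 1 TPM in both libraries.

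Genes of injury, early response and proliferation ranged from abundant to near 0. Spp1 (1414 ± 159) and Clu (377 ± 89.03) led the injury list, while Havcr1 (19.98 ± 6.32) and Lcn2 (6.195 ± 0.00707) were lower, and the list median was 19.98 ± 6.32 TPM. Immediate early genes had a median of 4.103 ± 0.209, with Dusp1 (42.8 ± 11.5), Zfp36 (27.6 ± 2.18), Junb (14.1 ± 2.35) and Jun (12.9 ± 2.43) highest and Fosb (0.085 ± 0.00707) lowest. Heat shock genes (median 32.9 ± 8.41) were led by Hsp90aa1 (74.4 ± 1.68), Hspb1 (56.1 ± 6.05), Hspa1b (34.6 ± 12.6) and Dnajb1 (31.2 ± 4.2). Proliferation genes were low, with a median of 0.905 ± 0.0636 and Cdk1 (1.53 ± 0.269), Aurkb (1.22 ± 0.09899), Ccna2 (1.19 ± 0.0636) and Plk1 (0.935 ± 0.106) as the highest. Circadian genes that peak with Dbp (median 12.7 ± 3.91) stood above those that peak with Arntl (median 3.68 ± 0.0247), a difference that was not tested. The first list was led by Nr1d1 (106 ± 19.2), Tef (89.5 ± 14.8), Dbp (80.5 ± 12.5) and Nr1d2 (15.3 ± 6.14), and the second by Clock (8.91 ± 0.693), Arntl (4.18 ± 0.361), Npas2 (3.18 ± 0.311) and Cry1 (0.945 ± 0.1202). Nr1d2 had 19.6 TPM in replicate 1 and 10.9 in replicate 2, yet its TMM-scaled counts differed by a ratio of 0.913.

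Genes that tell male from female kidney did not all read alike. The 4 Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 0 counts in both libraries, except for 3 counts of Kdm5d in replicate 2. Xist, which is transcribed from the inactive X chromosome of females, had 29.1 ± 3.23 TPM (GRCm38 chromosome X, 103460366 to 103483254). The limit of 3 counts was at most 0.175% of the counts of the X homolog of a Y-linked gene. In the male-biased list (median 13.97 ± 0.955 TPM), Kap was followed by Cyp4b1 (241 ± 19.8), Odc1 (229 ± 2.57) and Cyp2e1 (55.4 ± 1.07), while Slco1a1 had 0 TPM in both libraries. The female-biased list (median 126 ± 35.9) held Cyp4a14 (209 ± 14.5), Slc22a7 (165 ± 79.6), Slc7a12 (98.2 ± 7.83) and Prlr (56.3 ± 3.04). The labels give both sexes for both libraries.

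Transcripts known to lack a polyA tail were detected in these polyA-selected libraries. Rn7sk, Rmrp (759 ± 329) and Rpph1 (509.8 ± 323) were the highest of that list (median 255 ± 161 TPM), and all 3 were higher in replicate 1, of which Rpph1 was called as different (2.13-fold, 95% interval 2.03 to 2.24). Terc (0.030 ± 0.0424) rested on 0 and 1 counts. Rny1 and Rny3 had 0 TPM in both libraries, with 2 and 3 counts for Rny1 and 9 and 8 for Rny3. Both are shorter than the 200 nt limit of the labels, so their levels say nothing about polyA tails. Among transcripts retained in the nucleus (median 207 ± 41.5), Malat1 (436 ± 131) and Neat1 (409 ± 63.2) were far above Meg3 (16.6 ± 5.37) and Kcnq1ot1 (0.20 ± 0.0707).

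Both replicates gave similar levels for most genes. Gpx3 had 22232 TPM in replicate 1 and 20937 in replicate 2, and Kap had 6279 and 6151. Across 13994 genes with 1 TPM or more in at least 1 library, Pearson's r of log2(TPM + 1) was 0.976 and Spearman's rho 0.974. This correlation is across genes, and genes are not independent replicates. The median absolute log2 ratio of 13568 genes was 0.24, and 329 genes (2.42%) were 2-fold or more apart. The median log2 ratio of TPM, replicate 2 over 1, was -0.17, against 0.01 with TMM-scaled counts. The biological coefficient of variation depended on the filter, at 0.227 over 16768 genes and 0.138 over the 6975 genes at a TPM of 10 or more.

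**Figure D2:**
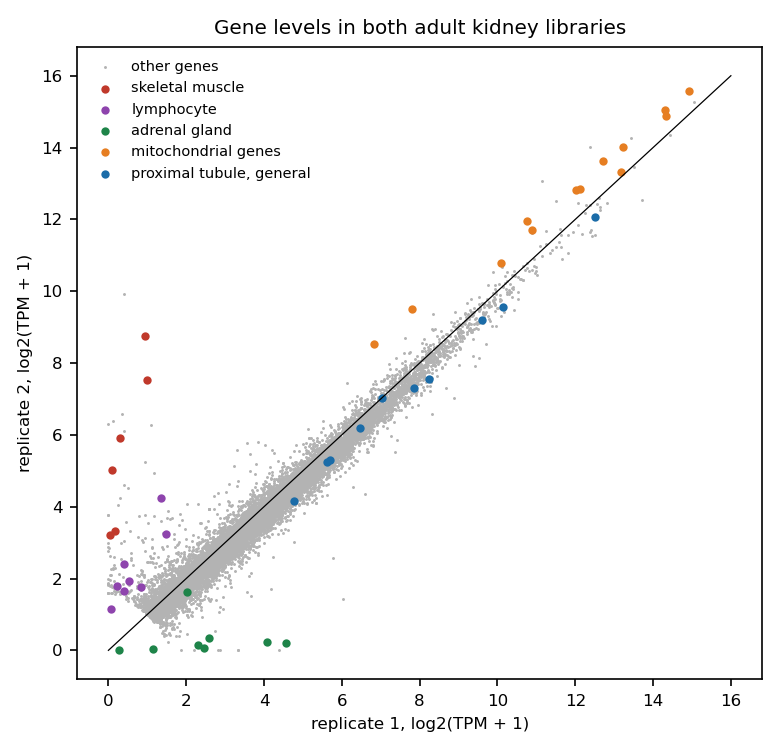
Level of each gene in replicate 2 against replicate 1, both as log2(TPM + 1), with the line of equal values and with genes of the skeletal muscle, lymphocyte, adrenal gland, mitochondrial and general proximal tubule lists in colour. Pearson's r of log2(TPM + 1) over 13994 genes was 0.976.

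Some lists moved between replicates beyond random lists of genes with like expression. The median log2 ratio, replicate 2 over 1, was higher by 5.46 for the skeletal muscle list, by 1.56 for the lymphocyte list, by 0.98 for the mitochondrial list and by 0.27 for the macrophage list, each relative to its matched random lists. Of 42 lists, these 4 lay above the central 95% of random lists and 11 below it, against 2.1 for lists of unrelated genes. Genes of 1 list can vary together, and some lists share genes such as Ren1, so more than 2.1 could lie outside. The 11 had relative shifts, replicate 2 over 1, of -2.14 for adrenal gland, -1.02 for smooth muscle, -0.92 for RNA not polyadenylated, -0.52 for connecting tubule and -0.42 for urothelium. They were -0.39 for fat, although Ucp1 of brown fat was 1.43-fold higher in replicate 2, -0.36 for renin-angiotensin-aldosterone, -0.32 for nuclear retained RNA and -0.32 for the late proximal tubule. For the thick ascending limb the shift was -0.26, and for the general proximal tubule -0.20. With TMM-scaled counts, the connecting tubule (-0.25) and nuclear retained RNA (-0.24) lists no longer lay outside, while the stroma (-0.21), red blood cell (0.36) and Dbp-phase (-0.21) lists did. With 1 library on each side these shifts carry no p.

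The other 27 lists stayed within the central 95%. Relative shifts among segments and cell types were -0.03 for the early proximal tubule, -0.15 for the thin limb, 0.06 for the distal convoluted tubule, -0.16 for principal and 0.17 for intercalated cells. They were 0.08 for podocytes, 0.06 for juxtaglomerular and macula densa genes, 0.10 for endothelium, -0.09 for stroma, 0.28 for red blood cells, -0.01 for liver and 0.08 for pancreas. The list of nuclear genes of oxidative phosphorylation shifted by 0.15, gluconeogenesis by -0.03, fatty acid oxidation by 0.12 and glycolysis by 0.00. Endocrine genes shifted by 0.05, transcription factors by 0.06, injury genes by -0.16, immediate early genes by 0.02 and heat shock genes by -0.01. Shifts were -0.16 for the Dbp phase, -0.04 for the Arntl phase and 0.04 for proliferation. The male-biased list shifted by 0.11, the female-biased list by 0.09 and Xist by 0.47.

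**Figure D3:**
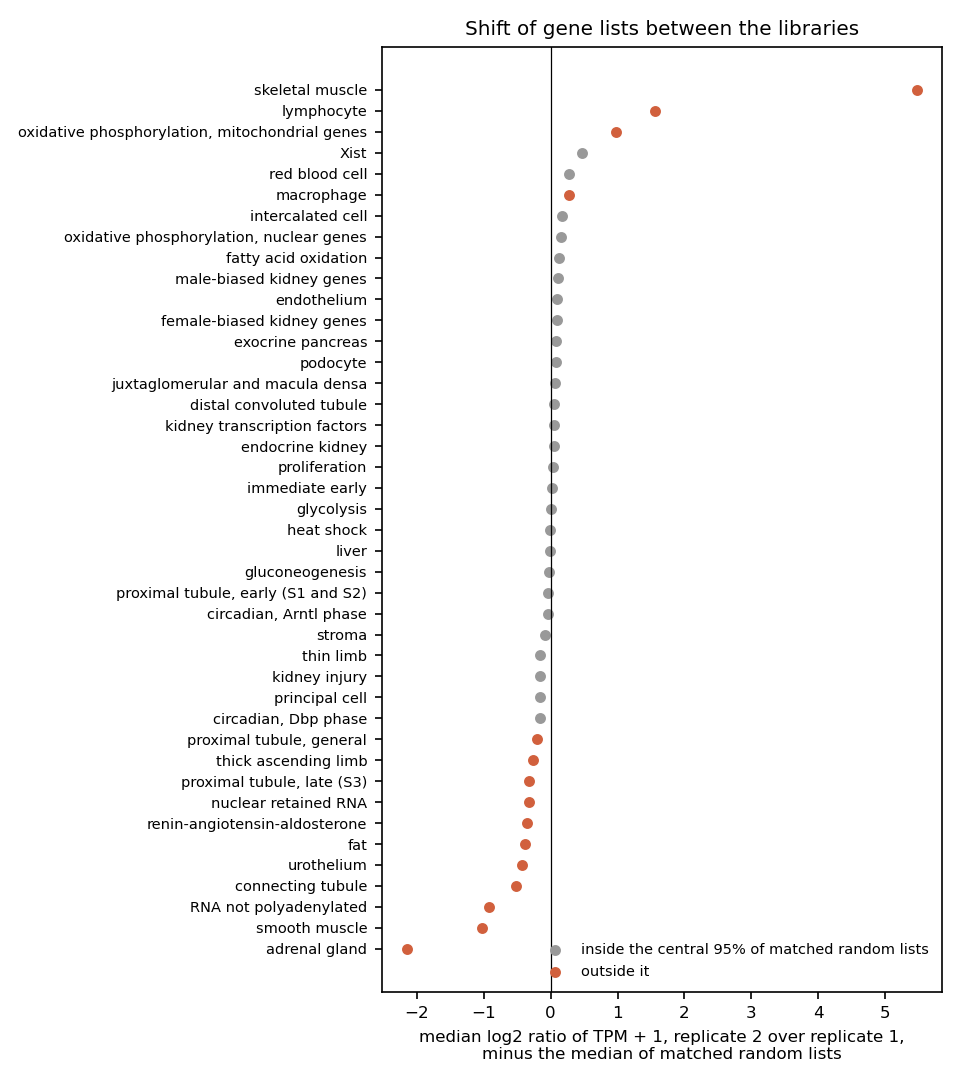
Shift of each gene list between replicates, as the median log2 ratio of TPM (replicate 2 over 1) minus that of matched random lists, with lists outside the central 95% of 10000 random lists in colour. Skeletal muscle (5.46) and adrenal gland (-2.14) lay farthest out.

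Genes of skeletal muscle, lymphoid cells and adrenal cortex differed most between the libraries. Acta1, the actin of skeletal muscle, had 0.93 TPM in replicate 1 and 429.7 in replicate 2, a ratio of 526 (95% interval 409 to 688; GRCm38 chromosome 8, 123891769 to 123894751). Glycam1, a mucin-like protein of lymph node vessels, had 0 counts in replicate 1 and 2505 in replicate 2, at least 678-fold higher when 3 counts are set for the 0 (95% interval from 551; chromosome 15, 103562759 to 103565081). In the other direction, Cyp21a1, the steroid hydroxylase of the adrenal cortex, had 22.5 TPM in replicate 1 and 0.15 in replicate 2, a ratio of 148 (95% interval 93.4 to 250.0; chromosome 17, 34801348 to 34804561). Hsd3b1 was likewise 108-fold higher in replicate 1 (95% interval 66.1 to 189; chromosome 3, 98852194 to 98859794).

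Of 18723 genes tested, 1442 (7.70%) differed between the libraries, 1000 higher in replicate 2 and 442 higher in replicate 1. This test compares libraries, not conditions, and it reads counting error alone, so that 10627 genes passed at any ratio. At a mean TPM of 5 or more, 126 genes differed, 100 higher in replicate 2 and 26 higher in replicate 1. Beside Glycam1 and Acta1, the largest ratios in replicate 2 were all of skeletal muscle genes. Tnnt3 had 1 count in replicate 1 (ratio 1509, 95% interval 270.5 to 59633), Tnnc2 had 2 (1256, 347 to 10377) and Sln had 3 (101, 34.4 to 493). The ratio was 363 for Atp2a1, 292 for Mylpf, 245 for Tnni2, 213 for Ckm and 109 for Casq1. Beside Cyp21a1 and Hsd3b1, the largest ratios in replicate 1 were 10.8 for Tmem254c, 6.65 for Gm13394, 6.47 for Fyb, 4.37 for Rpl39-ps and 4.12 for Gm4149. They were followed by Gm9843 (3.15), Gm2000 (3.15) and Gm15427 (3.11). Counts of Tmem254c, Gm13394 and Rpl39-ps were uncertain, and 13 of the 26 genes higher in replicate 1 were processed pseudogenes. For Fyb, TPM gave a larger difference (64.6 against 1.69) than counts (1313 against 250).

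Of the members of all lists, 35 differed between the libraries, and 35 also when adjusted over the list alone. All 6 skeletal muscle genes were higher in replicate 2, and 0 of them reached 1 TPM in both libraries. All 8 lymphocyte genes were too, among them Cd79a (1.55 TPM against 17.9), Lck (1.77 against 8.39) and Cd4 (0.44 against 2.81), with the value of replicate 1 first, and 2 of the 8 reached 1 TPM in both libraries. In replicate 1, 7 of 8 adrenal genes were called as higher, among them Star (5.0 TPM against 0.26), while Akr1b7 (2.58 ± 0.665), 1.28-fold higher there, missed the ratio limit and was the 1 gene of that list at 1 TPM or more in both libraries. Among mitochondrial genes, 7 of 13 passed, all higher in replicate 2 and mt-Nd3 and mt-Atp6 with uncertain counts, with mt-Atp8 3.55-fold higher in replicate 2 by counts but less so by TPM (20409 against 33772), and mt-Co1 (1.79-fold) and mt-Cytb (1.95-fold) short of the ratio limit. Pvalb (3.03-fold) and Lyz2 (2.32-fold) were higher in replicate 2. Acta2 (2.202-fold) and Cnn1 (4.99-fold) of smooth muscle were higher in replicate 1. The remaining called members were Rpph1 and, named after their values were seen, Hk2 of the glycolysis list (2.28-fold higher in replicate 2) and Ahsg of the liver list, which had 41 counts in replicate 1 and 0 in replicate 2, at least 16.8-fold higher in replicate 1 on the same basis (95% interval from 13.1).

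The leading isoform of most genes was the same in both replicates. Hnf4a-202 made up 92.0% ± 3.85 of Hnf4a transcripts (SD, n = 2) and Kcnj1-201 83.6% ± 4.48 of Kcnj1. Pkm-201 led at 82.5% ± 3.58, Slc4a4-207 at 80.1% ± 1.28 and Slc12a1-203 at 68.9% ± 0.0495. The leading isoform held less of Wt1 (Wt1-204, 55.5% ± 8.24), Vegfa (Vegfa-203, 38.8% ± 6.43), Wnk1 (Wnk1-204, 36.8% ± 1.61) and Fgfr2 (Fgfr2-217, 30.6% ± 5.48). The isoform list had a median of 116 ± 16.7 TPM, with levels from Pkm (448 ± 61.7), Vegfa (259 ± 54.1), Slc4a4 (129 ± 1.07), Wnk1 (106 ± 26.2) and Kcnj1 (46.4 ± 2.71) down to Wt1 (13.2 ± 3.39) and Fgfr2 (11.5 ± 1.34). Of 9388 genes with several isoforms, 8291 (88.3%) had the same leading isoform in both libraries and 1097 did not.

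Spike-in levels were closely correlated between the libraries. ERCC-00018 was the highest spike-in, at 3999 ± 1308 TPM, and ERCC-00136 the lowest above 0 in both, at 0.0250 ± 0.00707 TPM (SD, n = 2). Of 96 ERCC sequences, 70 were above 0 in both libraries. Over the 60 with 10 counts or more, r was 0.991 and rho 0.981 across sequences, whose levels spanned 9916-fold in replicate 1. Spike-ins took 1.59% of the counts of replicate 1 (Wilson 95% interval 1.585 to 1.591) and 2.29% of replicate 2 (2.288 to 2.294), a median of 1.56-fold more relative to nuclear genes in replicate 2. Single sequences did not shift alike, since this ratio on the log2 scale had a 10th percentile of 0.33 and a 90th of 1.73. Their amounts added are not given in the sources used here, so no absolute RNA amount was derived.

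Splice junctions and transcribed contigs were listed on the nuclear chromosomes and on chromosome M of mm9. The junction table lists 492582 junctions, 248443 on the plus and 244139 on the minus strand, with 25232776 R1 and 29635475 R2 counts. Both counts were above 0 for 193101 junctions (39.2%), which held 99.1% of the counts, and for these r of log2 counts was 0.937 and rho 0.934 across junctions. Junctions with flag A at 1 (167435, 34.0%) had a median of 48 counts, and 86.4% of them had both counts above 0. Junctions with flag A at 0 (325147, 66.0%) had a median of 1 count, and 14.9% had both above 0. The contig table lists 809659 contigs, 410693 on the plus and 398966 on the minus strand, with a total length of 290.2 Mb, a median length of 232 nt and a median level of 0.138. These tables were not tied to genes, since they are on another build and no annotation of mm9 was used here.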

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

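Tests chosen only after the results were seen are the junction test for chromosome Y, the test on Slco1a1 and Slc7a13, the TMM test on skeletal muscle genes, the count of further muscle genes without those of the largest ratios and the sum over mitochondrial genes and their copies, as was the choice of the 50 nearest genes for the match on length and GC content, made when narrower windows held no nuclear gene.

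Splice junctions on chromosome M held 7319 counts, 2273 of R1 and 5046 of R2, in data that no comparison of genes used and above the 3 counts that 0 allows. The ratio of R2 to R1 counts was 2.22 there and 1.17 over all junctions. Of 1988 such junctions, 255 had both counts above 0, and 28 had flag C at 1, with 7 R1 and 31 R2 counts. Whether junctions on chromosome M reflect splicing or alignment was not tested. Splice junctions on chromosome Y held 31 counts over 25 junctions, 2 of which had both counts above 0. The contig table, likewise used in no comparison of genes, lists 37 contigs on chromosome Y, with a median length of 80 nt and a median level of 0.102, against 0.138 over all contigs.

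Y-linked genes such as Ddx3y and Eif2s3y were at 0 beside Xist at 29.1 ± 3.23 TPM in libraries labelled as pooled from both sexes. A gene table made without chromosome Y would give this, and 0 of 1569 genes annotated on chromosome Y had more than 3 counts, although 10 were above 0. The junction table, which lists chromosome Y, argues against it, since junction counts on chromosome Y were 0.00342% of those on chromosome X, while the 4 X homologs take 2.14% of the gene counts of chromosome X. Low depth was excluded, since the limit of 3 counts was at most 0.175% of the counts of an X homolog. For a pool without males, Slco1a1 and Slc7a13, picked from the male-biased list after their values were seen, reached at most 0.570 TPM. Kap stood at 6215 ± 90.5 and Cyp4b1 at 241 ± 19.8 TPM, so this list decides nothing. The 4 Y-linked genes had at most 3 counts each in either library, a limit of at most 0.175% of an X homolog. For these genes, that argues against a sizeable share of male RNA in either library. With no group by sex no biological explanation was tested.

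Skeletal muscle genes such as Acta1 and lymphocyte genes such as Cd79a were higher in replicate 2, and adrenal genes such as Cyp21a1 in replicate 1. Scaling by the mitochondrial share was excluded as the cause, since the median log2 ratio of the muscle list was 8.26 with TMM-scaled counts, and 8.35 with genes under 3 counts set to 3. RNA from muscle may have entered replicate 2, as 87.5% of 16 further muscle genes were 4-fold or more higher, as were 83.3% of the 12 that are not among the 10 largest ratios, with 5 of the 16 at 1 TPM or more in replicate 1, and lymphoid RNA may have too, as 100% of 16 further lymphocyte genes, 4 of them at 1 TPM or more in replicate 1, were 2-fold or more higher. RNA of a whole adrenal gland in replicate 1 was argued against by 8 further adrenal genes, mostly of the medulla. Of these, 0% were 4-fold or more higher there, and Th (2.62-fold) and Dbh (3.11-fold) were higher in replicate 2. Of that list, 4 reached 1 TPM in replicate 2, among them Slc18a1 (95.8) and Mrap (18.5). Such levels make the 4-fold limit hard to pass, so the 0% says little for them. Mc2r (2.98-fold, 95% interval 1.82 to 5.01) and Mrap (1.58-fold) of the cortex were higher in replicate 1, so that cortex alone stays open. Passage of RNA between libraries was not tested, and no biological explanation was tested, since both replicates are of 1 group.

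Mitochondrial transcripts such as mt-Co1 and mt-Atp8 were higher in replicate 2. Reads shared with nuclear copies were excluded as the cause, since the sum over mitochondrial genes and copies was still higher by 0.82 on the log2 scale (1.77-fold). Gene length and GC content were argued against, since the mitochondrial list lay at percentile 100 of lists of nuclear genes matched on both (0.78 against a median of 0.07 and an upper limit of the central 95% of 0.34). The match left GC differences of up to 7.68 percentage points and log2 length differences of up to 1.36, so neither was excluded. The nuclear Gm42418 was also higher in replicate 2 (3.49-fold), and RNA quality was not tested, nor was a biological explanation.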

How the results depend on the processing

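Alternatives chosen only after the data were seen are the matching on length and GC content and the leaving out of the tissue, blood and mitochondrial lists. The share of TPM in the 10 highest genes was 15.3% without mitochondrial genes, with their nuclear copies kept and the mitochondrial genes taken out of the total. Without the copies too it was 8.24% of all TPM. The 10 highest genes held 12.4% of expected counts, and the mitochondrial share was 8.87% of expected counts. Replicate correlation was 0.959 with a pseudocount of 0.1, 0.992 with no filter and 0.975 with expected counts. The median absolute log2 ratio was 0.26 from a mean TPM of 10 and 0.0135 with no filter. It was 0.18 for expected counts scaled by TMM or by DESeq2 size factors, where the unit and the scaling changed together. The biological coefficient of variation was 0.275 with no filter and 0.138 from a TPM of 10. Genes that differ between the libraries numbered 867 from 50 counts, 10627 with no ratio limit and 634 at an absolute log2 ratio of 2, and an edgeR exact test with an assumed coefficient of variation of 0.1 gave 1095. With list members at 1 TPM or more only, 2 lists differed from the proximal tubule, and the juxtaglomerular list, then Ren1 alone, turned to 0.00751. Genes with the same leading isoform numbered 4809 from a TPM of 10 since fewer genes were compared, and 5356 where the lead held 60% or more in each library, a selection that also favours a shared lead. A replicate measure of 0.1 or less left 156990 junctions and 426458 contigs. For the other moved values the cause was not tested.

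Without either replicate in turn, detected genes ranged from 13521 to 13581, the share of the 10 highest genes from 17.3% to 25.0%, the mitochondrial share from 11.1% to 17.7%, and lists that differ from the proximal tubule were 11 each time. Leaving out the tissue, blood and mitochondrial lists gave 1409 differing genes, and matching on length and GC content 16 shifted lists, with intercalated cells (0.22) added. Gene levels from a single library were not counted, since with a pair they always lie within 1 SD of the mean. Across the remaining values of single genes and lists, 618 stayed within the spread or on their side of the threshold, 25 gene levels moved with posterior mean TPM, 13 calls appeared, 10 were lost and 1 reversed. Depth limits what can be read for genes with 3 counts or fewer, such as Pnlip. For the 4 Y-linked genes that limit was at most 0.175% of the counts of an X homolog.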

Other observations

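Genes in this part were chosen after their values were seen. Beyond the lists, H19, an imprinted transcript of embryonic tissue and adult muscle, was 35.6-fold higher in replicate 2 (1.26 against 29.5 TPM, replicate 1 first). The heavy chain genes Ighm (4.57-fold) and Ighd (15.3-fold), the T cell receptor genes Trbc1 (8.37-fold) and Trac (7.01-fold), and Ltb (8.45-fold) were higher in replicate 2, as was the chemokine gene Ccl5 (6.103-fold), and Ighd and Ltb also belong to the further lymphocyte list. Of muscle mitochondria, Ckmt2 was 78.7-fold higher in replicate 2.

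For the pseudogene Gm8325, TPM was 0.31 in replicate 1 and 972 in replicate 2, while its counts of 39.9 and 127 differed 2.59-fold. Both skeletal muscle lists together held 0.126% of the TPM of replicate 2. Of the adrenal cortex, Cyp11b2 was at least 6.31-fold higher in replicate 1, with 3 counts set for the 0 of replicate 2 (95% interval from 4.42).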
